A study of Rattus norvegicus with 8 samples.

How the data were processed

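RNA from dorsal root ganglion neurons of embryonic day 15 rats was sequenced after 7 days of culture in microfluidic chambers, devices in which axons grow through narrow grooves into a compartment of their own. The neurons had received a lentivirus with a short hairpin RNA against Pum2 (shPum2) or a control hairpin (shControl) at plating, per the labels. Each of the 4 groups, somatic and axonal compartment with either hairpin, held 2 libraries. The somatic libraries were made with a standard kit and the axonal libraries with an ultra-low input kit, per the labels, so compartment and kit cannot be told apart. The sample labels give the source of somatic RNA as cell bodies together with axons.

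The authors' deposited file of each library lists estimated counts from kallisto for 18321 RefSeq transcripts, per the file headers and the submitters' processing notes. The same deposited files give TPM, a length-scaled transcript share, which were not used in any test, and the transcript length and effective length in bases. The genome build Rnor_6.0 and the tools kallisto and DESeq2 are named in the submitters' processing notes, with no tool versions. Each of the authors' 2 deposited comparison tables, 1 per compartment, lists 17320 genes with a mean normalised signal, a log2 fold change of shPum2 over shControl, its standard error and test statistic (a score), and p-values with adjusted p-values, per the file headers.

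Transcripts were assigned to gene symbols through a RefSeq table of assembly GRCr8, used for names alone. Of the 18321 transcripts, 17367 (94.8%) matched. The other 954, with between 2.02% and 3.62% of the counts of a library, kept their own identifiers. Estimated counts were summed to 17379 genes and rounded to whole numbers. Reads shared by near-identical genes were divided by kallisto's estimate, so values of members of multigene families, such as Rasl2-9, Rn7sl1 and the ribosomal proteins, are uncertain.

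Tests used edgeR 4.0.16 in R 4.3.3: its quasi-likelihood test with TMM scaling and its expression filter, and Benjamini-Hochberg adjustment over the genes tested, with a threshold of 0.05. The shPum2 and shControl libraries were compared in a fit of the 4 somatic libraries and in another of the 4 axonal libraries. A fit of all 8 libraries gave the difference between the 2 knockdown effects (the interaction) and the axonal against the somatic shControl libraries. It used a single spread per gene for both compartments. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over lists. Of 28 lists, 26 had at least 5 tested members. DESeq2 1.42.0 was an alternative. Library-scaled counts (CPM) were taken over the total of each library. A fold against a group with 0 counts was computed from a floor of 3 counts over the group and is a lower bound. Intervals and floors cover counting error alone.

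The groups, tests, gene lists, rule for named genes and the first set of alternatives were fixed before the data were examined. The rule named Pum2, another gene that is not reported here and, per comparison, the 10 largest rises and 10 largest falls among genes past the threshold with non-overlapping libraries, a mean log2 CPM of at least 4 and a gene symbol. Where fewer than 5 passed in a direction, the genes with the smallest unadjusted p under the same limits were added up to 5. For the interaction, overlap was judged on the log2 CPM of each axonal library minus the somatic mean of the same hairpin. Up to 4 members per list with the smallest p could also be named. The alternatives were other size factors, no expression filter, DESeq2, limma voom, the replicate number as a block, each library left out in turn, a 2-fold limit, all 8 libraries in a single fit and, for lists, an estimated correlation, fry and other size factors. Others were added after seeing the data: scaling by total counts, the shPum2 libraries for the compartment comparison, and the mean of a fibroblast gene list as a covariate.

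The tests were run on simulated counts with 200 changed genes. A first simulation, with folds up to 16, recovered no changed gene in the interaction or compartment comparison, so it was replaced by larger folds for these and the axonal comparison. In the somatic comparison (12346 genes) 38% of genes changed 2-fold and 78% of those changed 4-fold were recovered, and 24 of 174 calls were false. The simulated libraries were drawn independently, whereas same-numbered somatic libraries deviated together across genes (r = 0.78). The real somatic test had 74 genes at an unadjusted p below 0.05, where 617 are expected. The simulated somatic rates may therefore not hold for it. In the axonal comparison (8517 genes) 2% were recovered at 4-fold, 14% at 16-fold and 56% at 256-fold, with 4 false calls among 65. The interaction (12337 genes) recovered 0% at 16-fold and 12% at 256-fold, and the compartment comparison (12337 genes) 2% and 28%. Apart from the 200 changed genes, the compartment simulation gave both compartments the same mean, whereas 3445 genes passed in the real comparison. Loss of transcripts beyond the fitted spread was not simulated. The axonal, interaction and compartment rates may therefore not hold for the real tests either.

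The total count per library was between 16725876 and 25821766 in the somatic and between 11641947 and 16131611 in the axonal libraries. A count of 0 allows up to 0.179 CPM in the shallowest somatic and 0.258 CPM in the shallowest axonal library. Nothing in the labels says that the 2 libraries of a group came from separate cultures, so p-values measure the spread between these samples, which may be technical. A planned search of 3′ untranslated regions for Pumilio binding elements was not run, since no transcript sequences were used here. Figures were drawn with matplotlib 3.10.9.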

Results

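The series measured RNA in the somatic and axonal compartments of cultured rat sensory neurons with and without knockdown of Pum2, a Pumilio RNA-binding protein known to bind 3′ untranslated regions and repress the mRNAs it binds. Each of the 4 groups had 2 libraries. Somatic libraries held totals of 16725876 and 23176678 counts with shControl and of 21254519 and 25821766 with shPum2. Axonal libraries held 11686666 and 13533385 counts with shControl and 11641947 and 16131611 with shPum2. At least 1 count was found for 14038 to 14263 genes in somatic and 9542 to 10730 genes in axonal libraries. The 10 most abundant genes took 5.9% to 6.6% of somatic counts and 24.3% to 30.4% of axonal counts. Across genes above a minimum count, which are not independent replicates, the log2 CPM of replicates correlated at r = 0.986 and 0.967 in the somatic groups but at 0.375 and 0.428 in the axonal groups. Over 6767 genes with a higher mean CPM, axonal libraries correlated at 0.62 and 0.65 within a hairpin and at 0.59 to 0.7 between hairpins.

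Pum2 was measured first in every library. In the somatic compartment it stood at 164 and 160 CPM with shControl and at 38.2 and 36.5 CPM with shPum2. It fell 4.36-fold, a log2 change of -2.13 with an SE of 0.07 and an adjusted p of 0.0247 (edgeR quasi-likelihood, Benjamini-Hochberg). Axonal Pum2 was at 3.25 and 0.443 CPM with shControl and at 1.46 and 7.07 CPM with shPum2. The axonal log2 difference was 1.25 with an SE of 2.37 (adjusted p = 0.9998, edgeR quasi-likelihood, Benjamini-Hochberg), and it was -0.75 without replicate 2 of axonal shPum2. The knockdown was therefore measured in somatic RNA and not detected in axonal RNA, where the values of the groups overlapped.

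**Figure D1:**
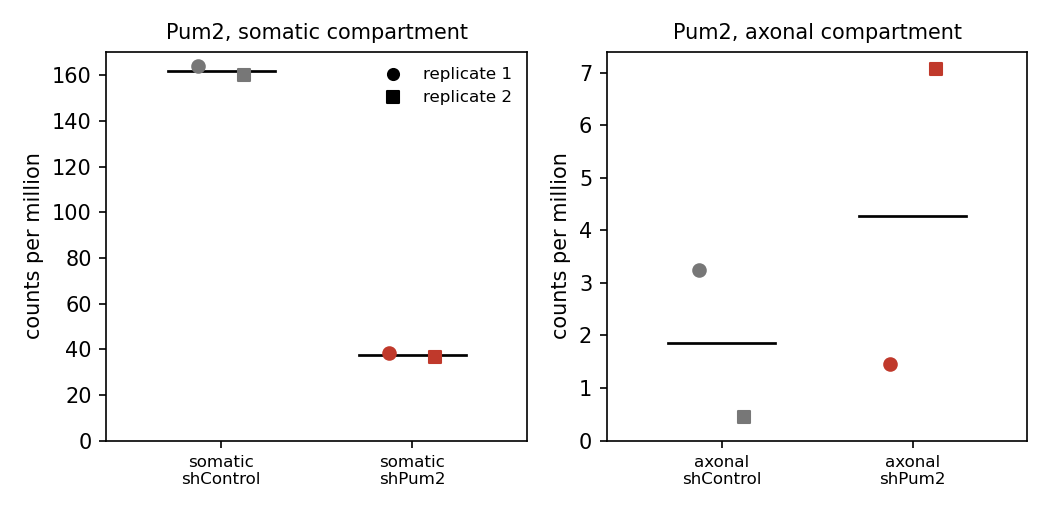
Pum2 in CPM (y axis) for each library (circles replicate 1, squares replicate 2), with the group mean as a line, for the somatic (left) and axonal (right) compartments. Somatic values drop from 164 and 160 to 38.2 and 36.5 with shPum2, while axonal values lie between 0.443 and 7.07 and overlap.

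The somatic comparison asked which RNAs change in cell bodies when Pum2 is reduced. Pum2 was the gene that passed the threshold among 12346 tested. Tac1, which encodes the substance P precursor of pain-sensing neurons, had 650 ± 19.1 CPM with shControl and 479 ± 17.1 CPM with shPum2 (SD, n = 2). Calca, the precursor of the neuropeptide CGRP, had 590 ± 75.7 and 435 ± 19.6 CPM. Prkcd, a protein kinase C, had 134 ± 15.8 CPM with shControl and 198 ± 6.11 CPM with shPum2. Serp1, a protein of the endoplasmic reticulum stress response, had 115 ± 3.69 and 148 ± 4.25 CPM. Sesn2, a stress-induced sestrin, had 70.5 ± 3.17 and 92.8 ± 10.2 CPM. Dbi was at 61.1 and 77.0 CPM on average. The protocadherin Pcdh17 averaged 202 and 162 CPM, Cnnm1 28.9 and 19.8 CPM, and Sytl3 72.5 and 56.2 CPM. Apart from Pum2, each gene named here missed the threshold, with an adjusted p of 0.9997 (edgeR quasi-likelihood, Benjamini-Hochberg). At an unadjusted p below 0.05 there were 74 genes, where 617 are expected by chance. That number was 15 and 32 without replicate 1 or 2 of shControl, and 247 and 1741 without replicate 1 or 2 of shPum2. DESeq2 called 2 genes, and 952 and 0 in the other splits of these 4 libraries, which mix the hairpins. The authors' deposited table also has 2 past 0.05, Pum2 and Tac1. Without either somatic shControl library, or with all 8 libraries in a single fit, Pum2 kept its log2 change, between -2.12 and -2.14, and no longer passed.

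Of the 26 lists, 16 passed camera in the somatic comparison, 8 in each direction, and 0 with an estimated correlation. The list of the integrated stress response and unfolded proteins had 27 of 28 members positive, with a median log2 difference of 0.14 (adjusted p = 6.43e-06, camera, Benjamini-Hochberg; adjusted p = 0.605 with an estimated correlation). Among its members Sesn2 had a log2 difference of 0.39, Atf3 0.73, Xbp1 0.23 and Hspa5 0.21, and 0 of 28 passed singly, also when adjusted over the list alone. This list's adjusted p was 0.179 without replicate 1 of shControl and 0.708 without replicate 2 of shPum2. The synaptic vesicle list had 2 of 28 members positive (median -0.08) and the voltage-gated ion channels 9 of 41 (median -0.14), with Rims2 of the first at -0.23. Both had an adjusted p of 4.52e-06 (camera, Benjamini-Hochberg) and of 0.605 with an estimated correlation. The sensory neuron list, with Tac1, Calca and Scn11a, had a median of -0.07 (adjusted p = 0.00106, camera, Benjamini-Hochberg; 0.605 as the p with an estimated correlation). Lists of glycolysis, microtubule transport, actin, oxidative phosphorylation and dendritic RNAs also passed as lower by camera, with medians between -0.09 and -0.03. Their adjusted p lay between 0.0012 and 0.0229 (camera, Benjamini-Hochberg), and between 0.605 and 0.747 with an estimated correlation. Without replicate 1 of shPum2 none of these 8 lists passed as lower by camera (Benjamini-Hochberg): ion channels had an adjusted p of 0.0651, sensory neuron genes 0.569, glycolysis 0.735 and dendritic RNAs 0.589, while synaptic vesicle (0.458), actin (0.569) and oxidative phosphorylation genes (0.0651) turned direction and microtubule genes passed as higher (0.0253). Glycolysis (0.405), microtubule (0.187), actin (0.127), oxidative phosphorylation (0.95) and dendritic (0.187) genes also missed the threshold without replicate 2 of shControl, actin (0.0997) and dendritic (0.0593) genes without replicate 1 of shControl, and dendritic genes (0.0591) without replicate 2 of shPum2.

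Among the somatic libraries, markers of cells other than neurons were highest in replicate 1 of shPum2. The fibroblast list, with collagens and Fn1, summed to 4522 and 2488 CPM in somatic shControl and to 10911 and 2492 CPM in somatic shPum2 libraries. The macrophage and blood list summed to 134 and 84 CPM, then 298 and 72 CPM. Fibroblast (median 0.80), cell cycle (0.82), macrophage (0.76), Schwann and satellite glia (0.50), interferon (0.42), p53 (0.38) and immediate early genes (0.28) passed camera as higher, with adjusted p between 4.52e-06 and 0.00785 (Benjamini-Hochberg), and between 0.605 and 0.652 with an estimated correlation. Without replicate 1 of somatic shPum2 all 7 turned direction to lower. The fibroblast, macrophage and cell cycle lists then passed as lower, with adjusted p of 9.17e-10, 9.04e-08 and 0.00241 (camera, Benjamini-Hochberg). Without replicate 2 of somatic shControl none of the 7 passed, with adjusted p between 0.0642 and 0.756 (camera, Benjamini-Hochberg). With the fibroblast list as a covariate, added after seeing the data, 18 genes passed: Prkcd (log2 change 0.58) and Serpinf1 (0.79) were higher, and 16 were lower. The lower genes were Pum2 (-2.12), Tac1 (-0.44), Calca (-0.47), Epha4 (-0.64), Ubr7 (-0.79), Ptgds (-3.87), Fbln1 (-0.86), Sparcl1 (-1.16), Col13a1 (-2.24), Cdkn1c (-0.91), Vtn (-1.23), Islr (-0.86), Slc6a13 (-1.5), A2m (-1.11), Pygl (-1.73) and a transcript without a symbol. Fbln1, Sparcl1 and Vtn encode proteins of the extracellular matrix. The covariate turned the direction of 5 of the 16, among them Fbln1 (0.51 without it), Cdkn1c (0.72), Slc6a13 (0.57) and Islr (0.18). It was computed from the same somatic libraries and differed between the hairpins. With a coefficient per hairpin and another for the covariate, the fit left a single degree of freedom to estimate the spread. Apart from Pum2, these calls therefore cannot be taken as effects of the knockdown.

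**Figure D2:**
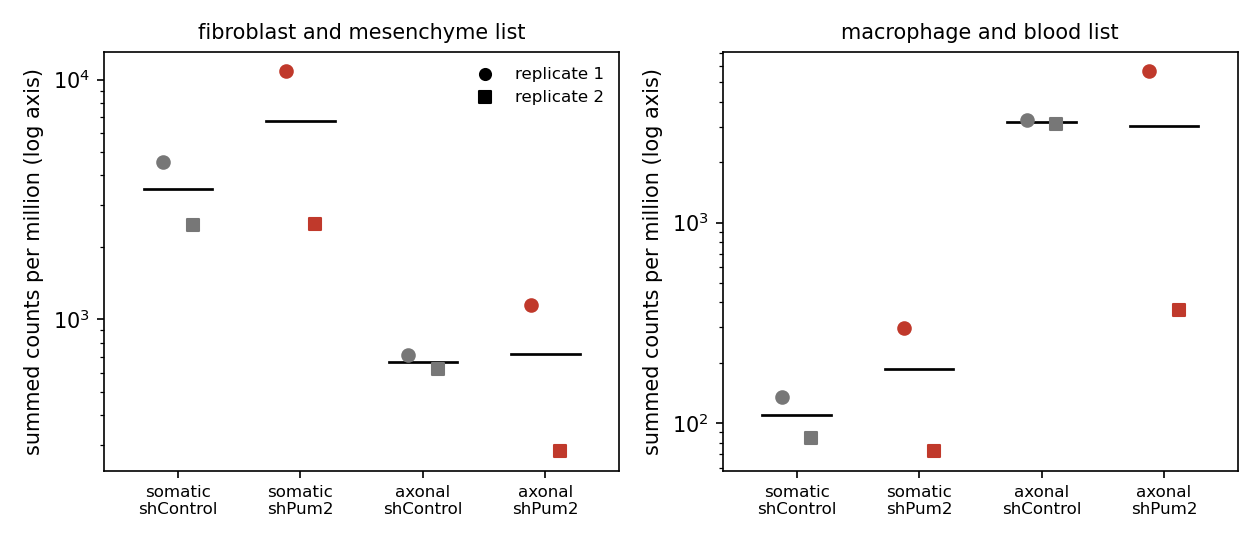
Summed CPM, on a log axis, of the fibroblast and mesenchyme list (left) and the macrophage and blood list (right) in each library (circles replicate 1, squares replicate 2), with group means as lines. Replicate 1 of somatic shPum2 holds 10911 CPM of fibroblast genes against 2488 to 4522 CPM in the other somatic libraries. Macrophage and blood genes, globin genes among them, sum to 3237, 3095 and 5724 CPM in 3 axonal libraries and 367 CPM in the other.

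The axonal comparison asked which RNAs change in axons when Pum2 is reduced, and no gene of 8517 passed. The receptor tyrosine kinase Epha2 was at 0.257 and 0.222 CPM with shControl and at 29.4 and 90.4 CPM with shPum2. Usf1, a transcription factor, was at 0.257 and 0.591 CPM and then at 58.2 and 51.6 CPM. Ldb2, a LIM domain binding protein, was at 0.171 and 0.591 CPM and then at 39.9 and 38.2 CPM. The proton pump subunit Atp6v0d2 had 3 counts in all with shControl and 1416 with shPum2, a ratio of 429 with a counting interval from 146 to 2080. Tars2, a mitochondrial threonyl-tRNA synthetase, averaged 2.76 CPM and then 67.3 ± 10.9 CPM (SD, n = 2). In the other direction, the general transcription factor Gtf2b was at 7.36 and 81.4 CPM with shControl and had 0 counts with shPum2, at least 436-fold lower. The kinase Tec, at 11.3 and 74.6 CPM and then 0, was at least 419-fold lower. Il2rg, the common cytokine receptor chain of blood cells, was at 17.2 and 122 CPM and then had 1 count. Rab20 was at 6.33 and 116 CPM and then had 2 counts, and Ubox5 was at 16.8 and 74.7 CPM and then had 3. None of these 10 genes passed, all with an adjusted p of 0.9998 (edgeR quasi-likelihood, Benjamini-Hochberg).

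At an unadjusted p below 0.05 there were 257 axonal genes, where 426 are expected by chance. DESeq2 called 157 genes, 82 higher and 75 lower, and edgeR without the expression filter called 6. The other splits of these 4 libraries, which mix the hairpins, gave more calls: 610 and 222 with DESeq2, and 14 and 17 with edgeR without the filter. The authors' deposited table has 357 genes past 0.05, 171 higher and 186 lower. Of the 329 found by symbol, 295 were below 1 CPM in both libraries of a group. Its log2 fold changes correlated with those of edgeR at r = 0.991 across 7681 genes, and at 0.623 across 11090 genes in the somatic table. Leaving out replicate 1 of axonal shControl gave 22 calls and leaving out replicate 1 of axonal shPum2 gave 31. None of the 26 lists passed. The cholesterol synthesis list had 19 of 24 members positive (median 0.61) and the microtubule and transport list 28 of 36 (median 0.39), each with an adjusted p of 0.456 (camera, Benjamini-Hochberg). Other lists leaned lower at the same adjusted p. Among them were immediate early (4 of 13 positive, median -1.34), cell cycle (4 of 17, median -1.05) and macrophage and blood genes (5 of 14, median -0.73). Earlier described Pumilio targets had 8 of 11 members positive (median 0.42, adjusted p = 0.731, camera, Benjamini-Hochberg), Pum2 itself among them at 1.25. In the somatic comparison, where the knockdown was measured, this list had 7 of 13 members positive (median 0.01, adjusted p = 0.235, camera, Benjamini-Hochberg). The biological coefficient of variation was 125% in axonal and 23% in somatic libraries.

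The interaction asked whether the effect of the hairpin differed between compartments. No gene of 12337 passed, and DESeq2 called 606. At an unadjusted p below 0.05 there were 964 genes, where 617 are expected by chance. This fit used a single spread per gene for both compartments. In it the axonal comparison had 2035 genes at an unadjusted p below 0.05, against 257 in the fit of the 4 axonal libraries. The number above 617 can therefore follow from the shared spread and cannot be read as effects that differ between compartments. L1cam, a cell adhesion molecule of growing axons, was at 4.36 and 4.73 CPM in axonal shControl and at 65.5 and 45.7 CPM in axonal shPum2 libraries, against 935 ± 41.6 and 935 ± 77.7 CPM in the somatic groups (SD, n = 2). The tubulin deglutamylase Agtpbp1 was at 1.57 ± 0.399 CPM and then at 45.6 ± 7.82 CPM in axons (SD, n = 2). Lrp11, a receptor-related membrane protein, was at 0.685 and 1.03 CPM and then at 53.3 and 27.2 CPM. Usf1 had the values given above, and Apbb3 was at 0.0856 and 0.148 CPM and then at 30.0 and 18.5 CPM. Trappc8, part of a vesicle tethering complex, was at 28.7 and 23.9 CPM in axonal shControl and at 0.172 and 0.186 CPM in axonal shPum2 libraries. Dnm1, the neuronal dynamin, was at 16.4 and 38.8 CPM and then at 0.945 and 0.434 CPM. The exosome helicase Mtrex was at 24.2 and 94.5 CPM and then at 0.601 and 0.310 CPM, and the cap methyltransferase Rnmt at 16.7 and 49.8 CPM and then at 0.258 and 0.124 CPM. These genes and Ubox5 all had an adjusted p of 0.329 (edgeR quasi-likelihood, Benjamini-Hochberg). Adjusted over the list alone, L1cam passed within the axon guidance and adhesion list (adjusted p = 0.00689, edgeR quasi-likelihood, Benjamini-Hochberg), and no other member of the lists did in the interaction. In the fit of the 4 axonal libraries L1cam had a log2 difference of 3.47 with an SE of 1.53. It did not pass there over the list alone (adjusted p = 0.764, edgeR quasi-likelihood, Benjamini-Hochberg). The interaction gave 3.53 with an SE of 0.46, which rests on the spread shared with the less variable somatic libraries. Without replicate 1 of axonal shControl 713 genes passed, 491 of them positive. None of the 26 lists passed, the smallest adjusted p being 0.217 (camera, Benjamini-Hochberg) for the immediate early and the microtubule lists. Across 8385 genes tested in both compartments, the fold changes correlated at r = -0.0543 and rho = -0.088, and the genes are not independent replicates.

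**Figure D3:**
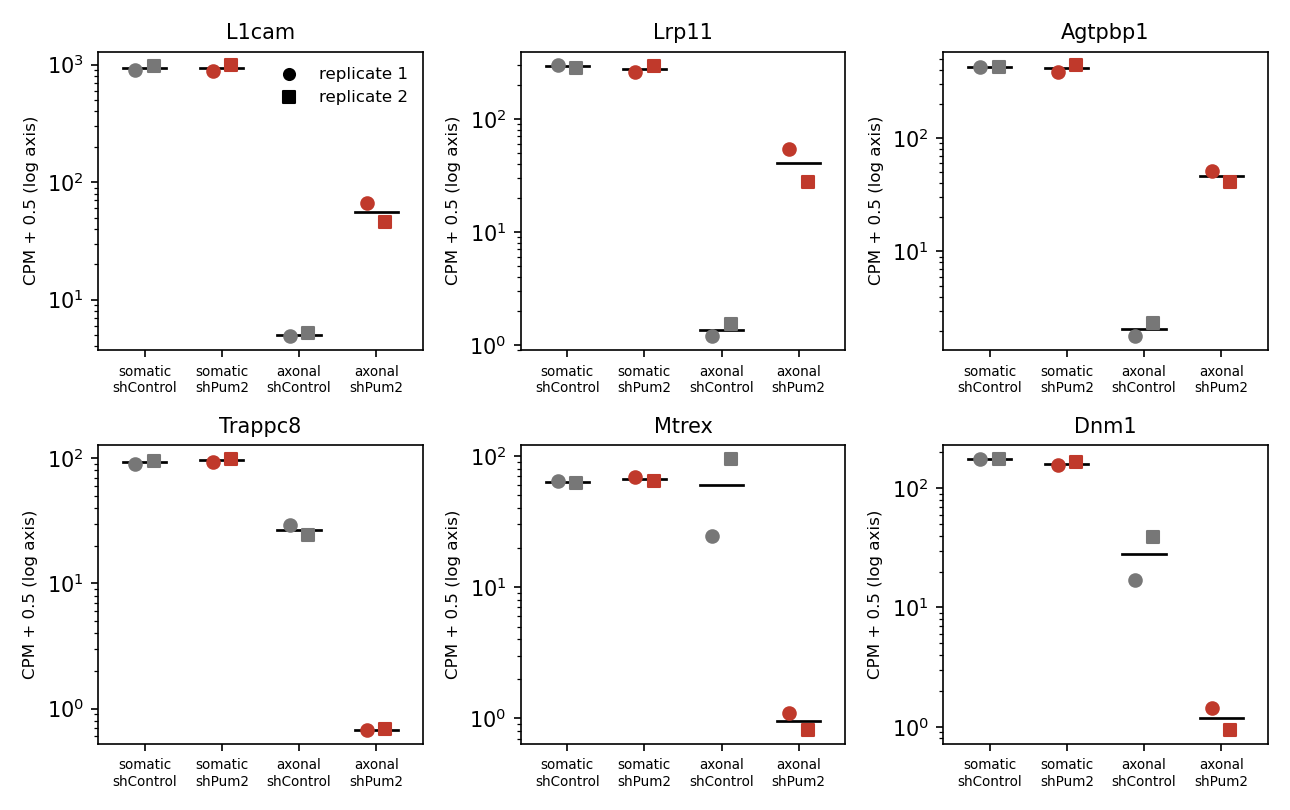
CPM plus 0.5, on log axes, of L1cam, Lrp11, Agtpbp1, Trappc8, Mtrex and Dnm1 in each library (circles replicate 1, squares replicate 2), with group means as lines. Somatic values differ little, for example 906, 965, 880 and 990 CPM for L1cam, while the axonal libraries separate by hairpin. The 6 genes were chosen for small p and non-overlapping axonal values relative to the somatic mean. Their separation by hairpin therefore follows from the choice. None of the 6 passed the interaction test over all genes.

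The compartment comparison asked which RNAs were higher in axonal than in somatic libraries of shControl cultures after TMM scaling. The TMM factors averaged 0.592 in axonal and 1.71 in somatic libraries. The log2 changes therefore lie above the ratios of the CPM values, which are shares of the total counts. The ribosomal protein and oxidative phosphorylation lists passed camera as higher in axonal libraries, and the ion channel, synaptic and adhesion lists as lower, though fewer than all members passed singly and each of these lists had an adjusted p of 0.373 or 0.588 with an estimated correlation. Of 12337 genes 3445 passed, 1161 higher and 2284 lower. The ferritin light chain Ftl1 was at 64400 ± 12700 CPM in axonal and 1270 ± 2.43 CPM in somatic libraries, the actin-binding Tmsb4x at 28200 ± 6650 and 2720 ± 50.1 CPM, and the RNA-binding protein gene Stau2 at 14000 ± 9110 and 252 ± 8.38 CPM (SD, n = 2). These 3 were chosen after their values were seen. Cytosolic ribosomal proteins had 68 of 77 members higher (median log2 change 3.32), with Rps2 at 16100 ± 4260 against 904 ± 7.94 CPM. Nuclear-encoded oxidative phosphorylation genes had 59 of 70 higher (median 4.04), with Ndufa1 at 1570 ± 401 against 47.1 ± 0.847 CPM and Cox7a2 at 2090 ± 489 against 96.6 ± 4.08 CPM. Adjusted over the list alone, 70 and 64 members were higher. Both lists passed camera, with adjusted p of 3.73e-38 and 6.31e-37 (Benjamini-Hochberg), and had an adjusted p of 0.373 with an estimated correlation.

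Ion channels had 24 of 41 members lower (median -5.65) and 27 when adjusted over the list alone. Cacna1h, a T-type calcium channel, was at 0.842 ± 0.586 CPM in axonal and 214 ± 9.18 CPM in somatic libraries. Axon guidance and adhesion genes had 15 of 43 lower (median -3.42), with L1cam at a log2 change of -6.10 and Dpysl2 at -2.93. Synaptic vesicle genes had 9 of 28 lower (median -2.22), among them Nrxn2 at -6.46 and Unc13a at -7.06. Dendritic RNAs had 7 of 14 lower (median -5.59), with Dlg4 at -6.23 and Grin1 at -6.36. These 4 lists had adjusted p between 1.41e-06 and 0.0151 by camera (Benjamini-Hochberg), and 0.373 or 0.588 as the p with an estimated correlation. The actin and growth cone list had 10 of 32 higher and 3 lower (median 0.07, adjusted p = 0.0223, camera, Benjamini-Hochberg; 0.373 as the p with an estimated correlation), with Tmsb4x at 4.97 and Tmsb10 at 5.03 against Dbn1 at -3.74. This list lost its call without replicate 2 of axonal shControl (adjusted p = 0.136, camera, Benjamini-Hochberg). Among sensory neuron genes, 8 of 26 fell, among them Scn10a (-6.41) and Trpv1 (-5.34), while the neurofilament gene Nefm rose by 2.01, and the list did not pass (adjusted p = 0.227, camera, Benjamini-Hochberg).

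Genes of other cell types were among the largest rises. The macrophage and blood list had 8 of 14 members higher (median 6.30, adjusted p = 5.63e-06, camera, Benjamini-Hochberg; 0.469 as the p with an estimated correlation), among them Lyz2, Fcer1g and Tyrobp, and Schwann and satellite glia had 3 of 14 higher and 1 lower (median 2.76, adjusted p = 0.0235, camera, Benjamini-Hochberg; 0.373 as the p with an estimated correlation). The glial mean log2 change was 0.91, and the list's adjusted p was 0.0522 (camera, Benjamini-Hochberg) without replicate 2 of axonal shControl. Glial genes summed to 4743 and 241 CPM in the axonal shControl libraries, of which Apoe took 4510 and 63.4 CPM. The 10 largest rises were Thsd1 (log2 change 11.26), Ins2 (10.86), Rgs1 (10.33), Rasl2-9, Rn7sl1 (10.23), Il2rg (10.15), the chemokine Ccl3 (9.50), Cdkn2c (9.25), the cannabinoid receptor Cnr2 (9.24) and the embryonic globin Hbe1 (9.15), of which Rgs1, Il2rg and Ccl3 are known from leukocytes. Rasl2-9 had 3 somatic counts against 859, a ratio of 453 with a counting interval from 154 to 2200. The 10 largest falls were Rhov, Rtn4r, Ctif, Rufy2, Mtmr7, Lrfn1, Crkl, Fbxo41, Rdh11 and Cdk17. Rhov had 0 axonal counts and 33.1 ± 0.477 CPM in somatic libraries (SD, n = 2), at least 279-fold lower, and the other 9 had 1 or 2 axonal counts. Adjusted p of these 20 genes ran from 0.003889 to 0.04646 (edgeR quasi-likelihood, Benjamini-Hochberg). Pum2 itself was lower in axonal libraries, with a log2 change of -4.85 and an SE of 1.44 (adjusted p = 0.0473, edgeR quasi-likelihood, Benjamini-Hochberg).

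**Figure D4:**
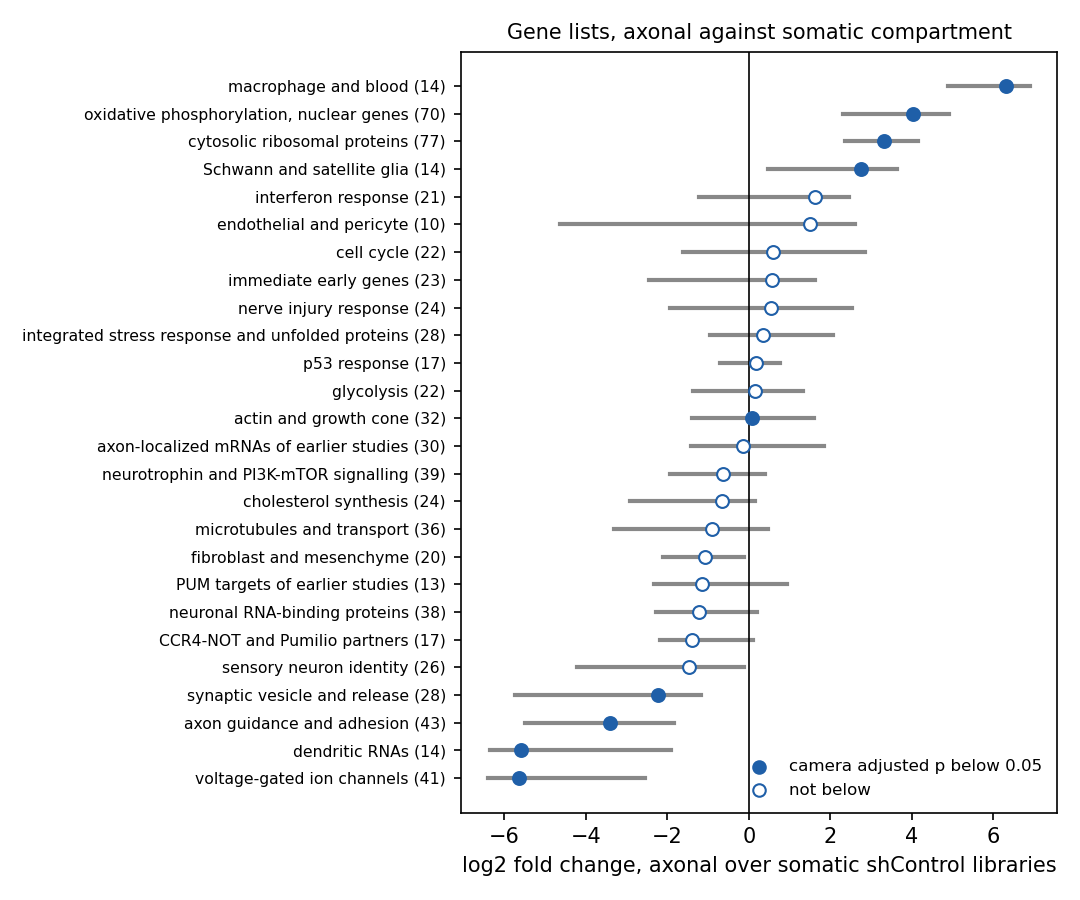
Median log2 fold change of axonal over somatic shControl libraries for the 26 gene lists (points), with the range from the first to the last quartile of members as lines and the number of tested members in parentheses. Filled points passed camera: macrophage (6.30), oxidative phosphorylation (4.04), ribosomal protein (3.32), glial (2.76) and actin (0.07, but below 0 and not passing with total-count scaling) lists as higher, and ion channel (-5.65), dendritic (-5.59), guidance (-3.42) and synaptic (-2.22) lists as lower, each with an adjusted p between 0.373 and 0.588 with an estimated correlation.

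The split of calls moved with the scaling and with the libraries. With total counts in place of TMM, an alternative added after seeing the data, the median of all genes shifted by -1.59 and 4215 genes passed, 14.4% of them higher in place of 33.7%, and the actin list's median fell below 0, with an adjusted p of 0.405 (camera, Benjamini-Hochberg). No gene passed edgeR without replicate 1 or without replicate 2 of somatic shControl, with 3438 and 3504 at an unadjusted p below 0.05, and 514 (81.1% higher) or 498 (82.5% higher) passed without replicate 1 or 2 of somatic shPum2, whereas 5539 and 5532 passed without an axonal shPum2 library. In the shPum2 cultures the same comparison gave 3046 genes, of which 2458 passed in both in the same direction, where independent lists would share 469. The comparisons of the 2 cultures came from the same fit, with the same spread per gene and the same kits. They are therefore not independent, and an overlap above 469 is partly built in. Across genes the fold changes of the 2 cultures correlated at r = 0.606.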

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

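All values in this part were looked at after the results were seen. Among 47 genes named by the rule, 6 had every somatic shPum2 library on 1 side of the somatic shControl libraries and every axonal shPum2 library on the opposite side, where chance gives 5.6%, or 2.6 genes. The genes had been chosen on values of the same libraries, Gtf2b, Il2rg and Mtrex on axonal differences between the hairpins and Rhov, Rtn4r and Lrfn1 as compartment falls with axonal shControl values near 0. The rule also required non-overlapping libraries, so genes picked on a hairpin difference were largely apart in a compartment beforehand. That chance number is therefore too low, and the 6 genes cannot be read as more than chance. The interaction test called none of them. Its adjusted p (edgeR quasi-likelihood, Benjamini-Hochberg) was 0.329 for Gtf2b, Il2rg, Mtrex and Rhov and 0.5723 for Lrfn1 and Rtn4r. Rhov was at 32.8 and 33.4 CPM in somatic shControl and at 27.9 and 32.6 CPM in somatic shPum2 libraries, and at 0 and 0 against 34.1 and 14.1 CPM in axons. Mtrex was at 63.6 and 61.9 against 69.0 and 63.9 CPM in somatic libraries, and at 24.2 and 94.5 against 0.601 and 0.310 CPM in axons. Gtf2b was at 28.6 and 24.9 against 30.3 and 28.8 CPM in somatic libraries and reached 0 in both axonal shPum2 libraries. Il2rg was at 0.12 and 0.216 against 0.235 and 0.349 CPM in somatic libraries. Lrfn1 reached 10.9 CPM and Rtn4r 8.68 CPM in a single axonal shPum2 library each.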

How the results depend on the processing

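The fibroblast covariate, the total-count scaling and the shPum2 compartment comparison were chosen after seeing the data, and the other alternatives before. For the somatic comparison, calls went from 1 to 2 with DESeq2, to 18 with the fibroblast covariate and to 0 with all 8 libraries in a single fit, where the Pum2 log2 change was -2.14. They ran from 0 to 1, with a Pum2 log2 change from -2.13 to -2.12, when each library was left out. Of the 16 somatic lists past camera, 0 passed with an estimated correlation, 0 with fry and 5 with the covariate. In all, fry passed 1 list, the earlier described Pumilio targets, which holds Pum2 itself, and the covariate 8. The number past camera ran from 6 to 17 when a library was left out. Without replicate 1 of somatic shPum2, 11 lists turned direction. With each library left out their adjusted p (camera, Benjamini-Hochberg) ran from 0.003 to 0.569 for actin, 1.68e-10 to 0.569 for p53, 5.43e-19 to 0.0642 for cell cycle, 3.36e-22 to 0.431 for fibroblast, 0.00086 to 0.456 for immediate early, 1.96e-05 to 0.828 for interferon, 2.55e-15 to 0.756 for macrophage, 8.62e-06 to 0.187 for microtubule, 0.000163 to 0.95 for oxidative phosphorylation, 5.82e-05 to 0.747 for glial and 6.32e-09 to 0.458 for synaptic vesicle genes. Oxidative phosphorylation also turned without replicate 2 of somatic shControl (0.95) and with the covariate (0.995), and macrophage genes with the covariate (0.295). For the axonal comparison, calls went from 0 to 6 without the filter and 157 with DESeq2, and ran from 0 to 31 when a library was left out. The Pum2 log2 difference then ran from -0.75 to 3.42, and lists ran from 0 to 3. The interaction went from 0 to 606 with DESeq2, from 0 to 713 when a library was left out, and its lists from 0 to 7. The compartment count ran from 0 to 5539 when a library was left out, and its lists went from 9 to 0 with an estimated correlation and ran from 7 to 10 without a library. DESeq2 gave 5072 and no filter 2620 compartment calls. With fry 12 compartment lists passed, 8 of them among the 9 past camera. The macrophage and blood list missed the threshold (adjusted p = 0.0767, fry, Benjamini-Hochberg), and the sensory neuron list was among the 4 newly passed (0.0315). The cause of these changes was not tested. Where a library was left out, the lone library of its group was assumed to vary like the others.

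Same-numbered libraries deviated together between the somatic groups (r = 0.78 across 6767 genes) and at r = 0.04 to 0.13 elsewhere. With 2 numbers per comparison this is a hint from the data and no pairing. With the replicate number as a block, calls were 1 somatic, 0 axonal, 0 interaction and 2370 compartment, and lists were 19, 0, 0 and 9, with Pum2 at -2.13 and 1.27 and 706 somatic genes at an unadjusted p below 0.05. Among single named genes and lists, 497 and 173 results kept side and direction, 101 and 73 no longer passed, and 38 genes and 0 lists newly passed. All alternatives for the Pumilio element search were not run, and those for files with TPM alone did not apply. Depth limits the lowest values, since a count of 0 allows up to 0.258 CPM in the shallowest axonal library, and how far it limits the axonal and interaction tests was not tested.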

Other observations

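Every test in this part was chosen after the results were seen, except the loss of transcripts within groups, whose bounds were set before its value was known. The second list of macrophage genes and the rule for the genes named next were also set after the results were seen.

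Some genes separated the axonal libraries by hairpin. With every shPum2 library at least 4-fold from every shControl library and a minimum of 10 CPM on the higher side, 150 genes were higher and 62 lower with shPum2. Of the higher genes, the 8 with the highest somatic CPM were L1cam, Pja2, Agtpbp1, Mapk6, Stx1a, Lrp11, Scn3b and Txnrd1. Stx1a, a syntaxin of synaptic vesicle release, was at 18.1 and 1.63 CPM with shControl and 111 and 98.6 CPM with shPum2, and the thioredoxin reductase Txnrd1 at 3.17 and 15.3 and then 98.6 and 89.1 CPM. The 8 on the lower side were Snx27, Dnm1, Pnpla3, Stau1, Pxdn, Stt3b, Kat7 and Trappc8. Stau1, an RNA-binding protein gene, was at 16.6 and 69.6 CPM and then at 3.61 and 2.73 CPM.

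The 4 axonal libraries allow 3 splits into pairs, all 3 of which gave at least the 212 genes of the real split, the highest other split giving 575, and the splits are too few for a share under 0.05. The split of 575 sets the replicate 1 against the replicate 2 libraries, with 517 of the genes higher in replicate 1, but the deviations of same-numbered axonal libraries correlated at r = 0.07 across genes, and whether the samples have such a structure stays open. Random loss of transcripts in low-input libraries may account for such genes: 26.4% of genes at 10 CPM or more in 1 library were below 1 CPM in the other within groups, against 23.4% across groups and 0.0% in somatic libraries. Whether somatic RNA carried into the shPum2 libraries raised the higher genes was not decided. They stood at medians of 60.4% and 53.4% of their somatic CPM there. They had been chosen for at least 10 CPM in both shPum2 libraries, at a median somatic CPM of 50, so high percentages follow from the choice. For 170 abundant somatic genes that were low in both control axonal libraries the medians were 5.3% (upper quartile 14.27%) and 0.29% (1.57%). These 170 were not chosen on shPum2 values, so the gap between the medians cannot argue against carry-over. In replicate 2 they leave little room for an even addition of all somatic RNA, unless transcripts were lost at random. Added RNA alone would not lower 62 genes, but the smaller sides of the other splits held 58 and 59. The 62 genes therefore cannot argue against carry-over. Of the 170, 33 were 4-fold higher in both shPum2 libraries. Genes chosen for low control values can rise through that choice alone, so this count decides nothing. Carried-over RNA stays open for the higher genes. In replicate 1 of shPum2, 2388 abundant somatic genes stood at a median of 30.8% of somatic CPM, against 14.5% to 22.0% in the other axonal libraries. An effect of the knockdown stays open as well.

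Replicate 1 of each somatic group may have held more non-neuronal cells. Of 4 lists of other cell types, 3 (fibroblast, glial and macrophage) had a lower quartile above 0 for replicate 1 minus replicate 2 in both groups, with medians of 0.91 and 2.14 on the log2 scale for fibroblast genes, 0.47 and 0.92 for glial genes and 0.67 and 1.95 for macrophage genes. Sensory neuron genes differed by 0.00 and -0.05. The explanation stays open, since the endothelial list, with 6 members, had 3 of 6 higher in replicate 1 of shControl (median 0.27, quartiles -0.21 and 0.83). No biological explanation was tested.

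Macrophages in the axonal compartment are a candidate source of the macrophage genes there. The macrophage and blood list also holds globin genes such as Hbb, which this candidate does not cover. Of 22 other macrophage genes, in none of the earlier lists, 72.7% were at least 4-fold higher in the mean of the axonal than of the somatic libraries. In 10000 random sets matched on somatic CPM the median was 13.6% and the 95th percentile 27.3%. Genes of a cell type can vary together, which such sets leave out. The means also hide differences between libraries. In replicate 2 of axonal shPum2, Spi1 was at 0.062, C5ar1 at 0 and Cybb at 0.31 CPM, though Cd53 was at 65.3 and Itgb2 at 34.5 CPM. Ly86 (21.1, 0, 0 and 0 CPM) and Msr1 (0, 0, 49.1 and 0.062 CPM) counted through a single axonal library each, with shControl values given first. Lyz2 was at 816, 2190, 2060 and 172 CPM, but Csf1r was at 153, 0.296, 252 and 0.310 CPM and C1qc at 0.222 and 0.062 CPM in both replicate 2 libraries. A lower neuronal share would raise fibroblast genes alike, but the medians lay 7.38 apart on the log2 scale, against an interquartile range of 2.01. Noise of the low input and an effect of its kit stay open.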
